A study of Danio rerio with 2 samples.

How the data were processed

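The series compares 1 sample of zebrafish lens with 1 sample of bodies without eyes, both at 10 days after fertilization, each on 1 one-colour array. Per the series' design text the samples stand for 191 lenses and 20 bodies. That each set was pooled into 1 RNA is implied by the single array per tissue and not stated. Per the labels' protocols, total RNA was isolated with TRIzol and a column kit, then amplified and labelled with Cy3 using a low input kit. The arrays were scanned and read with Feature Extraction 10.7.1.1, per the file headers, whereas the submitters' processing notes name version 9.5.1.1. Both arrays came from 1 slide and 1 scan, per the file headers, so slide and scan do not separate the tissues.

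The deposited processed signals are intensity values on a linear scale, background-subtracted and detrended within each array, with small values replaced by a surrogate and no scaling between arrays, per the file headers. The deposited mean spot signal and median local background are unprocessed intensity values, per the file headers. The other deposited columns used are flags of 0 or 1 per spot, per the file headers, for being well above background, saturated or an outlier. The value table that the authors deposited with the series is also intensity on a linear scale. Both of its columns have a median of 104.8 and the same distribution, so its values were quantile normalized and not centred. Its log2 values correlated with the processed signals of the same array with r = 0.991 for the lens and 0.999 for the body, and with those of the other array with 0.684 and 0.696. Differences between its columns correlated with those after quantile normalization of the processed signals with r = 0.997. How it was made is not given in the sources used here.

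Control spots (1417 per array) were left out, as were 2 outlier spots on the lens array and 6 on the body array. The other 43803 spots, less those outliers, gave 43603 probes after averaging spots of 1 probe. The main value of a probe was its log2 processed signal minus the 75th percentile over all non-control probes of the array. Gene names were taken through RefSeq accessions from a table of the GRCz12tu assembly, of which only names were used. The own accession named 59.3% of probes, another accession of the probe 5.34%, a current symbol 9.38% and an older synonym 1.90%, while for 8.94% the name in the file was kept. In all, 37000 probes carried 20249 gene names and 6603 probes had none. The accessions of 400 probes named more than 1 gene. Probe positions are those of the files, on Zv9. No annotation of that build was used here, so whether a probe lies in an exon or an untranslated region was not determined.

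The value of a gene was that of its probe with the highest mean signal over both arrays. A gene entered if this probe was well above background on at least 1 array. Where it was not well above background on 1 array, the difference is a bound: the brighter signal against the higher of the dim probe's own signal and the lowest signal of any probe well above background on that array. After scaling, these lowest signals were −4.87 for the lens and −6.23 for the body. A bound that pointed the wrong way gave no order. A gene was called at a difference of 2-fold or more, with bounds called in their direction: 280 of the genes called higher in the lens and 2463 of those called lower rest on bounds. All 280 genes above background on the lens array only were called higher. These calls were nearly fixed in advance, since the lowest signal of the lens lies more than 2-fold above that of the body. The error of a difference combines the spot errors that Feature Extraction gave for both arrays. Replicate spots of 1 probe differed by a median SD of 0.079 (28 probes, lens) and 0.064 (38 probes, body) on the log2 scale. Of 4967 called genes with more than 1 probe above background, 278 called genes had a probe called the other way.

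Before the data were examined, 29 gene lists were fixed, together with the alternatives and the rule for naming genes. The rule took the 10 genes per direction with the greatest difference measured on both arrays and the 6 per direction with the greatest bound. From each list it took the 2 highest and 2 lowest members measured on both arrays and the 2 greatest bounds. It also took detected PLAAT genes and hsf4. Placeholder names were not eligible, and crystallins were named only from their list. List members were matched by symbol, synonym or pattern. Capital letters were ignored, since the files write genes of mitochondrial DNA in capitals, a change made after the list was first found empty. Also after the fact, ptgs1, ephb2b and mcm3ap were removed from lists because an old synonym or a pattern had matched a different gene. Genes in more than 1 list include pla2g1b (phospholipases and pancreas), hsp90b1 and hspa5 (chaperones and endoplasmic reticulum), eno3 and pgam2 (glycolysis and muscle), eno2 (glycolysis and neurons), pdia2 (endoplasmic reticulum and pancreas), cahz (inner retina and erythrocytes), gfap (inner retina and neurons) and ttr (pigment epithelium and liver). Single results of 2 genes are not reported here, while their values still count in the lists.

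For each list the median difference was set against the medians of 10000 random lists of the same size, matched on mean signal in 20 bins. The percentile describes these 2 arrays and is not a test. The match held within 0.26 log2 for all lists except the ribosomal one, whose mean signal was 3.22 above that of its random lists, and the mitochondrial DNA list, 1.71 above. The 95% interval of a list median is the binomial interval from its ordered members and covers only the spread between genes. With 1 array per group no model was fitted and no other split of the samples exists.

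In all, 17 alternatives were computed. They comprised 8 other scalings or sources: the median, the 75th percentile over probes above background on both arrays, quantile normalization, no scaling, spike-in probes, normexp with an offset of 50 before the 75th percentile or quantile normalization, and the authors' value table. The filter on dim probes, the outlier and saturated spots, the probe rule, the threshold (4-fold, or 2-fold beyond 2 spot errors) and the matching of random lists were also varied. Python 3.11.15, numpy 2.4.6, pandas 2.3.3, scipy 1.17.1 and matplotlib 3.10.9 were used, with limma 3.58.1 in R 4.3.3 for normexp.

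The gene step was tested on simulated data over 18316 genes. Both simulated arrays were made from the body array's signals, and the lens array gave only the offset and the lowest signal. The changed genes were drawn from those well above background on the body array, so genes seen only in the lens were not covered. Of 100 genes raised by 3 on the log2 scale 100% were called, with a median of 2.99. Of 100 genes lowered by 3, 87.0% were called, with a median of −3.02, and 0% of unchanged genes were. The last value was close to fixed in advance. The simulated noise was small beside 2-fold, and the simulated offset was the one that the scaling removes. A difference between the arrays that grows with brightness was not simulated. A list holding raised genes reached the 100th percentile of random lists and an unchanged list the 53.3rd. That 100th percentile and the 100% called were also close to fixed in advance, as a rise of 3 lies far beyond this noise. Real genes differed far more between the arrays than the unchanged simulated ones, so the list step was not tested at that spread. The array headers give a spike-in fit with a slope of 1.00 for the lens and 0.974 for the body.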

Results

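Transcript levels in the lens were set against those in the rest of the body of wild-type zebrafish larvae at 10 days after fertilization. The lens sample stands for 191 lenses and the body sample for 20 bodies without eyes, and each sample was hybridized to 1 one-colour oligonucleotide array. The comparison asks which genes the lens, a tissue of an epithelium and of fibre cells that fill with crystallin proteins and lose their organelles, transcribes more or less than the remaining tissues together. There were no replicates, so no test was possible and no p-value is given. Genes are called higher or lower by size alone, at 2-fold or more, and 1 array per tissue limits the precision. The error given with a difference is that gene's own spot error (log2, median over genes 0.20, 5th to 95th percentile 0.20 to 0.31), which covers the measurement of a spot and not differences between animals or dissections.

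Both arrays carried the same 43603 probes. On the lens array 67.2% of them were well above background, and on the body array 86.6%. The 75th percentile of the probe signals was 211 on the lens array and 925 on the body array, and signals were compared after dividing by it. No spot was saturated on either array. The crystallins took up 15.9% of the summed probe signal of the lens array and 0.00535% of that of the body array. The 100 brightest probes held 29.2% of the lens signal and 20.0% of the body signal. Across probes, which are not independent replicates, the log2 signals of the arrays correlated with r = 0.693.

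Of 18478 genes well above background on at least 1 array, 14064 were so on both, 280 on the lens array only and 4134 on the body array only. A value or a bound was obtained for 17499 genes, and the other 979 had no order. In the lens 4876 genes were higher by 2-fold or more and 4904 were lower, while 7719 lay within 2-fold. Here and in the lists, genes within 2-fold include those with only a bound below 2-fold, whose true difference may be larger. Among the 78 genes more than 1000-fold higher in the lens, 56 were crystallins or other lens fibre genes. Another 42 genes were more than 1000-fold lower. The split depended on the scaling: it was 6844 higher against 4037 lower after scaling to the median, and 3636 against 5731 after scaling to the 75th percentile of probes above background on both arrays. With a normexp background and the 75th percentile it was 5372 against 2773, without scaling 822 against 14027, and after scaling to spike-in probes 382 against 16921. Keeping only genes above background on both arrays gave 4596 against 2441. The median difference of all compared genes was 0.15 in the main setting, and these scalings shifted it by 0.47, −0.34, 0.34, −2.07 and −3.30. No scaling, spike-in scaling, median scaling and the 75th percentile of probes above background on both arrays move all genes alike, so a sign that turns only under those says nothing of a group relative to the other genes. A gene called here by a small difference is called relative to the typical probe of its array.

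**Figure D1:**
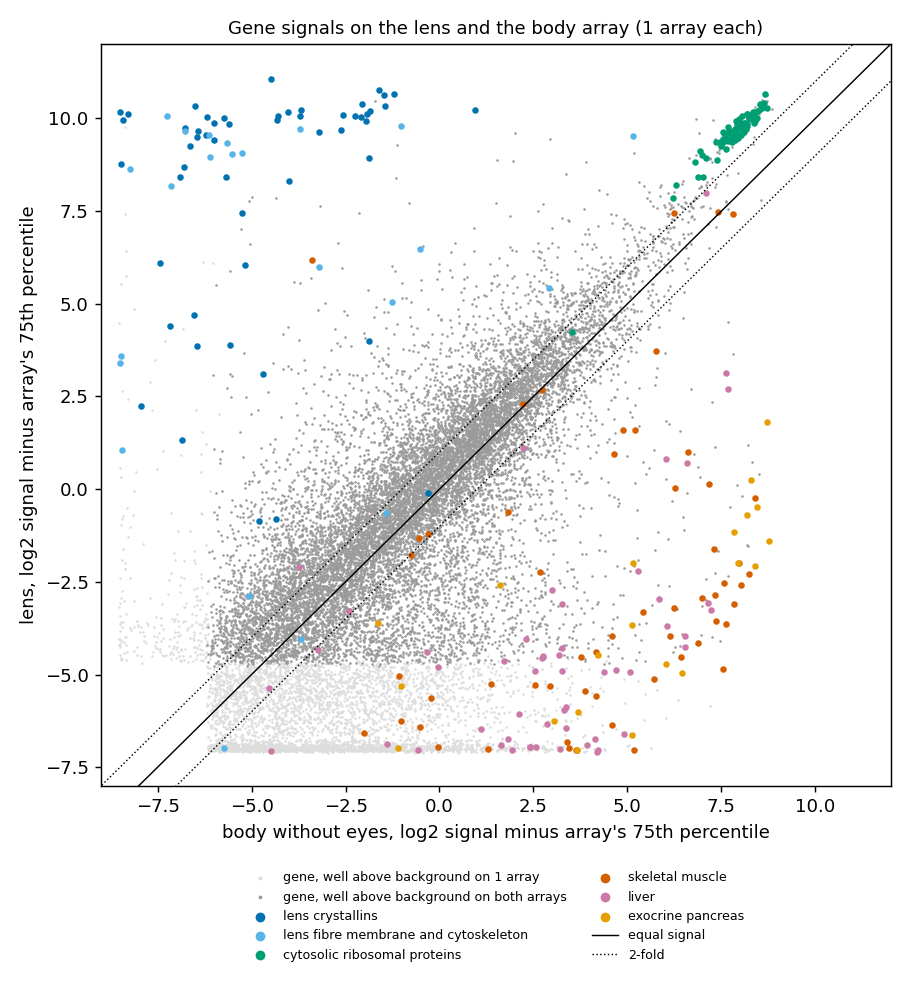
Signal of each gene on the lens array (vertical axis) against the body array (horizontal axis), both as log2 signal minus the 75th percentile of the array, with 1 array per tissue and 1 point per gene. Crystallins (median difference 12.56) and lens fibre genes (10.31) lie far above the line of equal signal and muscle genes (−8.04) far below it, each with the same sign under all 8 other scalings.

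The crystallins, the refractive proteins of the lens, were the group highest in the lens. Of 54 crystallin genes, 53 were higher in the lens and 1 lay within 2-fold. Their median log2 difference was 12.56 (95% binomial interval over genes, 12.12 to 14.29), above that of all 10000 random lists matched on signal, and it stayed above 9 under every scaling tried. The body array did not rise above background for 19 of them. The beta crystallin cryba2a, whose probe lies on chromosome 6 (13691125 to 13691184, Zv9), was at least 96359-fold higher, and the gamma crystallin crygmx at least 86749-fold. Among those measured on both arrays, crygm2c differed by 15.86 ± 0.34 and cryba1b by 15.72 ± 0.29 (log2, spot error). The exception, crybb3, differed by 0.18 ± 0.20, and its other probe was lower in the lens by a bound of −2.23.

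Genes for the membrane, junctions and cytoskeleton of lens fibres followed. Of 22 compared, 20 were higher in the lens and none was lower, with a median of 10.31 that kept its sign under all 8 other scalings. The lens intrinsic membrane proteins lim2.4 and lim2.3 were at least 80353-fold and at least 61375-fold higher. The water channel gene mipa was at least 21979-fold higher, and mipb at least 52549-fold higher by its brightest probe, although its other probe was measured on both arrays with a difference of 7.07. For dnase1l1l, a DNase, the bound was 34411-fold, and for the glutamine-synthetase-like gene lgsn 29953-fold. Among genes measured on both arrays, lim2.1 was higher by 32737-fold, and lim2.5 differed by 14.55 ± 0.28, the galectin-related grifin by 14.31 ± 0.25 and the beaded filament gene bfsp2 by 13.44 ± 0.21. The members nearest to 0 were caprin2 at −0.36 ± 0.27 and epha2a at 0.77 ± 0.20. Outside the lists, the genes with the greatest lens excess on both arrays included lctla (14.01), lenep (12.88), jac9 (12.84), jac8 (12.22), ifnphi4 (11.64) and otc (11.47).

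Transcription factors of lens development were divided. Of 25 compared, 12 were higher in the lens and 9 lower, with a median of 0.54 that fell within the middle 95% of matched random lists and turned negative without scaling and with spike-in scaling. The forkhead factor foxe3 was 198-fold higher and the homeodomain factor pitx3 97.9-fold higher, in all 3 of the pitx3 probes. The heat shock factor hsf4 was at least 329-fold higher in the lens, by a probe on chromosome 18 (22527957 to 22528152, Zv9). In contrast, dlx3b differed by −6.60 ± 0.29, eya1 by −6.03 ± 0.32 and foxg1a by a bound of −5.11.

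Phospholipases, among which the PLAAT family was to be named whatever its value, were divided as well. As a list of 40 genes they showed no common direction, with 16 higher, 11 lower and a median of −0.24, which turned positive after median scaling, quantile normalization, both normexp settings and in the authors' value table, and relative to all genes only under both normexp settings. The PLAAT gene plaat1 was 774-fold higher in the lens (9.60 ± 0.20), by a probe on chromosome 11 (46231104 to 46231163, Zv9), and its other probe gave a bound of 13.93. The related gene plaat1l was not well above background on the lens array and had no order. The phospholipase D family gene pld3 differed by 5.27 ± 0.21. At the other end were plcb4 at −5.20 ± 0.28, abhd3 at −3.78 ± 0.28, pnpla3 with a bound of −6.20 and plcb3 with a bound of −3.29, the last with 3 of 5 probes lower.

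Lists for other routes of protein and organelle turnover moved little. Of 34 autophagy genes 11 were higher and 2 lower, with a median of 0.63 that turned negative without scaling and with spike-in scaling and lay at the 84.3rd percentile of matched random lists. The microtubule-associated light chain gene map1lc3c stood apart at 5.98 ± 0.21. Lysosome genes were split 9 to 9 among 37, with a median of 0.07 whose sign changed under 6 of the 8 other scalings. Relative to all genes it was −0.08, and it stayed between −0.42 and −0.08 under those scalings. Among them the hexosaminidase gene hexa was 90.6-fold higher in the lens and the cathepsin gene ctsl.1 274-fold lower. Of 41 proteasome genes 9 were higher and 1 lower, with a median of 0.63 that turned negative without scaling and with spike-in scaling, and lay at the 28.9th percentile. Their median relative to all genes, 0.48, turned to −0.08 after quantile normalization and in the authors' value table and to −0.11 with a normexp background and the 75th percentile. The lower gene was psma6l at −4.69 ± 0.31. Heat shock proteins and chaperones (70 genes) held 23 higher and 17 lower, with a median of 0.40 that turned negative under 5 of the 8 other scalings. The chaperone median relative to all genes was 0.25 and turned negative after quantile normalization, under both normexp settings and in the authors' value table, down to −0.20. The range ran from dnajb6b at 4.13 ± 0.20 and hspa8b at 3.88 ± 0.20 to the muscle chaperone gene unc45b at −7.38 ± 0.25 and hspb9l at −7.81 ± 0.32.

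Cell cycle genes were higher in the lens as a group. Of 28 compared, 18 were higher and 1 lower, and the median of 1.14 (95% binomial interval over genes, 0.79 to 1.64) lay at the 99.9th percentile of matched random lists. That median turned negative without scaling and with spike-in scaling, at −2.21 in the latter, but relative to all genes it stayed between 0.78 and 1.31 under the 8 other scalings. The cyclin genes ccne2 and ccnb2 differed by 4.14 ± 0.27 and 2.71 ± 0.23. The lower gene was mcm3l, with a bound of −2.07. Near 0 were mcm7 at 0.08 ± 0.20 and birc5a at −0.44 ± 0.22.

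Genes for ribosomes and for oxidative phosphorylation stood high in the main setting, and after quantile normalization the ribosomal excess was gone and the others were smaller. All but 1 of 78 ribosomal protein genes were higher in the lens, with a median of 1.77 (SD over genes 0.21), which turned to −0.06 after quantile normalization and in the authors' value table, −0.07 with normexp and quantile normalization, −0.36 without scaling and −1.58 with spike-in scaling. Relative to all genes it was −0.25 after quantile normalization, but 1.56 without scaling and 1.57 with spike-in scaling, near the 1.62 of the main setting. The highest was rpl5a at 2.18 ± 0.20 and the exception rpl7l1, taken in by the pattern of its symbol, at 0.70 ± 0.20. Of 34 other genes as bright, 28 were also higher, with a median of 1.71. The 9 genes of mitochondrial DNA were all higher, from ND6 at 1.33 to ND4 at 2.11, with a median of 1.64 that turned negative without scaling and with spike-in scaling. Relative to all genes, that median stayed positive under all 8 other scalings, and it dropped from 1.49 to 0.07 after quantile normalization. Of 98 nuclear genes of oxidative phosphorylation, 42 were higher and 5 lower, with a median of 0.87 that turned negative without scaling and with spike-in scaling and lay at the 74.5th percentile. The muscle and heart isoform gene cox6a2 had a bound of −7.24.

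Of 32 genes for protein folding in the endoplasmic reticulum, 14 were lower in the lens, 3 higher and 15 within 2-fold. The median of −0.70 lay below all 10000 matched random lists and stayed negative under all 8 other scalings. The disulfide isomerase genes pdia8 and pdia4 differed by −3.47 ± 0.32 and −2.23 ± 0.20, whereas pdia2, which is also in the pancreas list, had a bound of −8.53. The stress factors xbp1 and atf4a differed by 1.19 ± 0.20 and 1.18 ± 0.20, and both turned negative without scaling and with spike-in scaling. Glycolysis (37 genes) held 7 higher and 12 lower. Its median of −0.12, at the 0.970th percentile, turned to 0.23 after median scaling, but relative to all genes it was −0.27 and stayed between −0.73 and −0.28 under the 8 other scalings. The binomial interval of the glycolysis median over genes, −0.934 to 0.381, held both signs. The muscle aldolase gene aldoab and the neuronal enolase gene eno2 were lower by 1143-fold and 158-fold, while pkma and eno1a differed by 1.82 ± 0.20 and 1.79 ± 0.20. Sterol synthesis (22 genes) held 5 higher and 8 lower, with a median of −0.71, at the 2.78th percentile, that turned to 0.08 with a normexp background and the 75th percentile. Relative to all genes it was −0.86 and stayed between −0.92 and −0.26 under the 8 other scalings. The binomial interval of the sterol median over genes, −1.527 to 0.689, held both signs. The squalene epoxidase gene sqlea was 9.82-fold higher and the HMG-CoA reductase gene hmgcra 16.1-fold lower.

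Markers of neighbouring eye tissues were mixed. Of 37 photoreceptor genes 16 were higher on the lens array and 6 lower, with a median of 0.28 that turned negative with the 75th percentile of probes above background on both arrays, without scaling and with spike-in scaling. It was 1.19 after quantile normalization, 1.304 with a normexp background and the 75th percentile and 1.11 in the authors' value table. Relative to all genes it was 0.13 and stayed positive under all 8 other scalings, from 0.06 to 1.005. The rod opsin gene rho was 29.4-fold higher, in 8 of 8 probes, and the ultraviolet cone opsin gene opn1sw1 15.7-fold. The rod transcription factor gene nrl was at least 1492-fold higher and the red cone opsin gene opn1lw1 at least 42.9-fold. Lower were gngt1 at −2.53 ± 0.33 and pde6gb at −2.44 ± 0.21. Inner retina and Mueller glia genes (22) held 4 higher and 12 lower, with a median of −1.32 that stayed negative under all 8 other scalings. However, the binomial interval of that median over genes, −2.746 to 0.815, held both signs. The highest and the lowest gene measured on both arrays were grm6b at 1.71 ± 0.21 and prdm1a at −4.76 ± 0.26. Genes of the retinal pigment epithelium and pigment cells (19) were split 5 to 5, with a median of 0.42 that turned negative without scaling and with spike-in scaling. Among them slc24a5 was 35.3-fold higher, in both of its probes. The highest, otx2b at 6.91 ± 0.21, rested on 1 probe, and 3 of its other probes were lower in the lens.

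Epidermal and corneal genes were mostly lower. Of 39 compared, 29 were lower and 7 higher, with a median of −4.83 that stayed negative under all 8 other scalings. The keratin genes krt5 and krt4 were lower by 1083-fold and 1048-fold, in all of their 6 and 9 probes. The lens excess of ppdpfa, 5.16 ± 0.20 by its brightest probe, was contradicted by its other probe at −3.47. The aldehyde dehydrogenase gene aldh3a1 differed by 3.41 ± 0.21.

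Genes of the large tissues of the body were far lower in the lens, and each median in this paragraph stayed negative under all 8 other scalings. Many members were dim in the lens and had only a bound: 8 of pancreas, 19 of muscle, 30 of liver and 19 of intestine. With dim signals taken as measured, these medians were −8.925, −8.29, −8.165 and −7.43, in that order. All 21 genes of the exocrine pancreas were lower (median −8.69), with the carboxypeptidase genes cpa5 and cpa4 at least 2554-fold and at least 1706-fold lower and the elastase gene ela2 lower by 1434-fold. For amy2al1 this rested on the brightest probe (−4.18), while its other probe was higher in the lens (4.28). Of 56 skeletal muscle genes 48 were lower (median −8.04), with the fast myosin gene myhz2 at least 5401-fold lower, the slow myosin gene smyhc3 lower by 2431-fold and the creatine kinase gene ckma by 1914-fold. Against this, mybpc1, a slow muscle myosin binding protein gene, was 761-fold higher in the lens by its only probe above background, and mybpc2b was 2.32-fold higher by 1 probe and lower by 2 others. Of 54 liver genes 49 were lower (median −7.29), with the apolipoprotein genes apobb.1 and apoa1b lower by 1740-fold and 1453-fold. Of 29 intestinal genes 25 were lower (median −6.12), led by afp4 at least 4305-fold and apoa4b.1 at least 2359-fold lower. The gene with the greatest body excess measured on both arrays was apoda.2, an apolipoprotein D gene, at −11.55 ± 0.29.

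The remaining lists were lower in the lens by less, with medians again negative under all 8 other scalings. Members dim in the lens, with only a bound, were 18 of brain, 6 of heart and 8 of immune cells. For cartilage, bone and connective tissue they were 18, for erythrocytes 6 and for endothelium 6. Of 53 genes of brain neurons and glia 44 were lower (median −4.02), with snap25a, a synaptic vesicle fusion gene, at least 414-fold lower and th and chga the only 2 called higher, th with 1 probe in each direction. Heart genes (14) had a median of −3.90, with 10 lower and 1 higher. The binomial interval of the heart median over genes, −5.996 to 0.526, held both signs. The atrial and ventricular myosin light chain gene myl7 was 88.8-fold lower. Immune genes (29) had a median of −3.09, with 20 lower and 3 higher, and the leukocyte plastin gene lcp1 was 39.9-fold lower. Cartilage, bone and connective tissue genes (38) had a median of −2.81, with 28 lower and 5 higher. There the collagen gene col1a1b was 139-fold lower, and cnmd differed by 3.91 ± 0.20 and was higher in both of its probes. The probes of col11a1a were divided: it was 19.1-fold higher by its brightest probe and higher by 1.41 (log2) in another, with 2 other probes lower. Erythrocyte genes (18) had a median of −2.41, with 11 lower and 2 higher. The binomial interval of the erythrocyte median over genes, −5.819 to 0.493, held both signs. This median turned to 0.32 (−0.14 relative to all genes) when only genes above background on both arrays were kept. The alpha globin gene hbae1.1 was 443-fold lower, whereas hbba2 was 19.8-fold higher by 1 probe, its others being dim on both arrays. Endothelial genes (25) had a median of −1.93, with 14 lower and 4 higher, and pecam1a differed by −5.66 ± 0.33 and cldn5a by 2.40 ± 0.21.

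**Figure D2:**
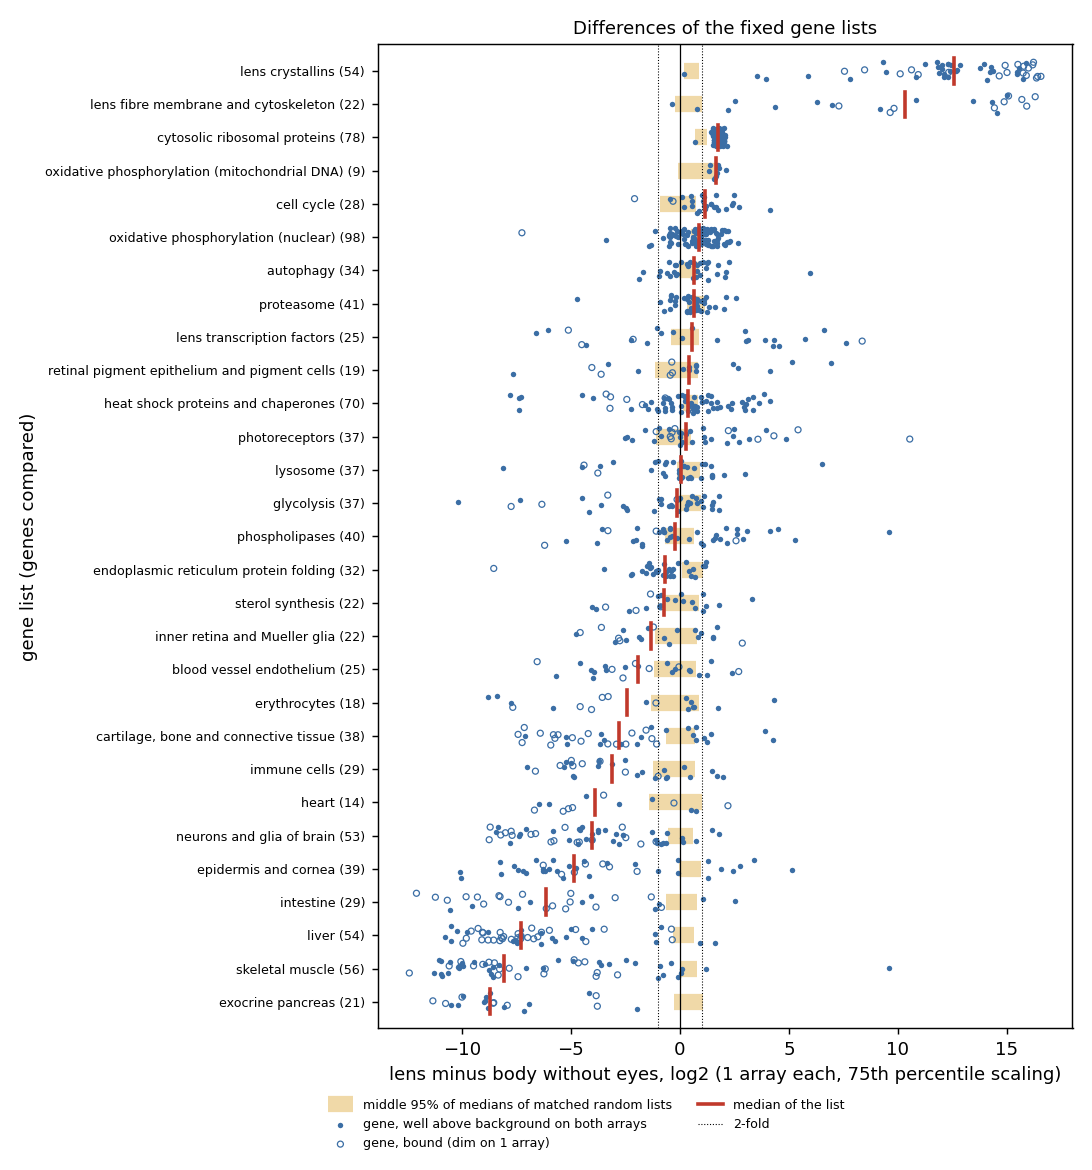
Lens minus body difference (log2, horizontal axis) of every compared gene in the 29 lists (vertical axis), with 1 array per tissue, filled points for genes measured on both arrays, open points for bounds, red bars for list medians and tan bars for the middle 95% of medians of random lists matched on signal. Medians run from −8.69 for exocrine pancreas to 12.56 for crystallins, both with the same sign under all 8 other scalings, while the ribosomal median of 1.77, from a list 3.22 brighter than its random lists, turns negative after quantile normalization with either background and in the authors' value table, and also without scaling and with spike-in scaling, where all genes move alike and it stays 1.56 and 1.57 above their median.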

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

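The alternatives were fixed beforehand, but the 95% interval over members, used below to say that a list median moved, replaced the median spot error after list medians had been seen under them. List medians are given here relative to the median of all compared genes. Of 406 such values under the alternatives, 368 stayed inside that interval, and 157 moved by more than the spot error of 0.20. Many of the 406 could hardly move, so the 368 overstate how far the medians hold. Scalings that move all genes alike nearly cancel in a relative median. Leaving out saturated probes or dropping the filter on dim probes left every compared gene as it was. No paired analysis was possible because there was 1 array per tissue and no test. Dim signal limits the lens array most: 67.2% of its probes were well above background, so 2463 of the genes called lower are called by a bound. Leaving out genes with saturated probes changed nothing, as there were none. Dropping the filter on dim probes could change no count, since a gene dim on both arrays gets no value.

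The count of genes higher in the lens was 4876 and of genes lower 4904. A 4-fold threshold gave 1982 and 3252, no scaling 822 and 14027, and spike-in scaling 382 and 16921. The count of lower genes was 2773 with normexp and the 75th percentile, and 2441 when only genes above background on both arrays were kept, which leaves out every bound. The count of higher genes was 2973 with normexp and quantile normalization. Of the 4876 genes higher in the main setting, 4279 were also higher after quantile normalization and 4219 in the authors' value table, and of the 4904 lower, 4147 and 3984 were also lower.

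The ribosomal median, 1.62 relative to all genes, reversed to −0.25 with quantile normalization, −0.13 with normexp and quantile normalization and −0.24 in the authors' value table. It was 1.56 without scaling, 1.57 with spike-in scaling, 1.01 with normexp and the 75th percentile, 1.31 for genes above background on both arrays, 1.57 for the mean of probes and 1.53 for the probe with the smallest difference. In the order quantile normalization, normexp with the 75th percentile, normexp with quantile normalization, the authors' value table and genes above background on both arrays, the crystallin median (12.41) was 11.92, 11.31, 10.57, 11.38 and 11.85. In that order the proteasome median (0.48) was −0.0766, −0.11, 0.0464, −0.0774 and 0.17. The nuclear oxidative phosphorylation median (0.72) was 0.20, 0.20, 0.32, 0.20 and 0.41, and the mitochondrial DNA median (1.49) was 0.0720, 0.89, 0.23, 0.0745 and 1.18. The liver median (−7.43) was −5.53 with normexp and the 75th percentile, −5.67 with normexp and quantile normalization and −6.10 for the probe with the smallest difference. With normexp and quantile normalization the intestine median (−6.27) was −4.18 and that of neurons and glia (−4.17) −2.80. The latter was −2.53 for the probe with the smallest difference. Cartilage, bone and connective tissue (−2.96) gave −1.44 for genes above background on both arrays and −1.18 for the probe with the smallest difference. Endoplasmic reticulum folding (−0.84) gave −0.43 for the mean of probes. Against random lists not matched on signal, the percentile of nuclear oxidative phosphorylation rose from 74.5 to 100, that of mitochondrial DNA from 94.4 to 99.3 and that of glycolysis from 0.970 to 20.9.

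Single genes reversed mainly where the whole array shifted. Without scaling these were psmd4a (−0.0083), ND4 (−0.0268), ND3 (−0.33), ND6 (−0.80), COX1 (−0.76), rplp2b (−0.0394), rpl19 (−0.71), pkma (−0.32), eno1a (−0.35), insig1 (−0.33), xbp1 (−0.95), atf4a (−0.96), grm6b (−0.42), mybpc2b (−0.92), a2m3g (−0.50), cdhr5a (−1.06), slc4a1a (−0.37), th (−0.35), chga (−0.64), rag2 (−0.13), cd4-1 (−0.41) and kdr (−0.69). With spike-in scaling they were ulk1a (−1.11), hexb (−0.37), psmd8 (−0.78), psmd4a (−1.23), ndufa5 (−0.68), ndufa6 (−1.07), ND4 (−1.24), ND3 (−1.54), ND6 (−2.02), COX1 (−1.97), rpl5a (−1.17), rplp2b (−1.26), rpl19 (−1.92), pkma (−1.54), eno1a (−1.56), sqlea (−0.0556), insig1 (−1.55), xbp1 (−2.16), atf4a (−2.18), ccnb2 (−0.65), grm6b (−1.64), mybpc2b (−2.14), a2m3g (−1.72), ada (−0.82), cdhr5a (−2.28), slc4a1a (−1.59), th (−1.56), chga (−1.86), rag2 (−1.35), cd4-1 (−1.62), cldn5a (−0.95) and kdr (−1.91). The gene rpl19 also reversed with quantile normalization (−0.0302), with normexp and quantile normalization (−0.16) and in the authors' value table (−0.0244). Where probes of 1 gene disagreed, the mean of probes reversed otx2b (−1.83), mybpc2b (−3.92), a2m3g (−0.17), amy2al1 (0.0488), slc4a1a (−1.22), th (−0.44) and col11a1a (−1.83), and the probe with the smallest difference reversed bnip3 (0.77), pmela (0.0914) and ppdpfa (−3.47). No scaling, spike-in scaling, median scaling and the 75th percentile of probes above background on both arrays move all genes alike by construction, and the probe rules exchange one probe for another. For the other moves the cause was not tested here.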

Other observations

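The gene families in the next paragraph were chosen after their values were seen, and so were the tests of a constant offset, of brightness in genes of any kind, of spike-in sensitivity and of the share of crystallins. The tests of carried-over retina and of bright probes being compressed were written before.

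Some groups outside the fixed lists, picked for their values, had most members on 1 side. Among wnt genes this held for the group picked, wnt2b and wnt7 (5 of 6 higher, median 3.84), and not for the whole family. Of 47 hox genes, which pattern the trunk, 39 were lower in the lens and 3 higher, and 32 of the 47 had only a bound, with a median of −3.06 that stayed negative under all scalings tried. The genes hoxa4a and hoxd10a were called higher by 1 probe and lower by 2 others. Of 6 fibroblast growth factor receptor genes, 5 were higher: fgfr3 by 4.08, fgfr1b by 3.55, fgfr2 by 3.35, fgfr4 by 3.25 and fgfr1a by 1.33, while fgfr1bl had a bound of −1.50. Their median of 3.30 turned to −0.05 only with spike-in scaling. Of 25 semaphorin genes 16 were higher and 5 lower, from sema6ba at 4.89 to sema4e with a bound of −6.16, with a median of 2.01 that turned to −0.12 without scaling and −1.78 with spike-in scaling. The wnt genes, which encode secreted ligands, had no common direction, with 7 of 20 higher, 8 lower and a median of −0.32. The members highest in the lens were wnt2ba at 5.32 and wnt7ba at a bound of 5.26, and wnt9a was the lowest at −3.42. Of 7 jac genes 6 were higher, with jac9 at 12.84, jac8 at 12.22 and jac6 at 9.11, jac11 at 1.54 with 2 other probes lower, and jac10 with a bound of −2.53. The median of the jac genes stayed positive under all scalings tried.

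Photoreceptor transcripts on the lens array could come from retina carried over with the lenses. The median difference of the photoreceptor list, 0.28, decided nothing, since a value above 1 was needed for carry-over and one below 0 against it, although it was 1.19 after quantile normalization, 1.304 with normexp and the 75th percentile and 1.11 in the authors' value table. Of 43 members 32 were well above background on the lens array, with rho at 1.18, opn1sw1 at 2.07 and nrl at 4.31 in scaled log2 signal, while gnat1, saga and crx were not. Among all 18478 genes 14344 were well above background on the lens array, a similar share, so the count does not set photoreceptor genes apart. With no eye sample, it is open whether dim probes work, and the body sample may hold photoreceptors of the pineal organ. Transcription of some of these genes in the lens itself was not tested and also stays open.

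The excess of ribosomal protein genes on the lens array may follow brightness more than gene function. The list lay at the 100th percentile of its random lists, which was meant to argue against compressed bright probes, but those lists averaged 3.22 dimmer (log2), so the comparison was not between genes as bright and leaves that explanation open. Set against 34 other genes as bright, the list median was only 0.06 higher, within its SD of 0.21, and the median difference of other genes ran from 0.23 at mean signals of −2 to 0 up to 1.74 at 8 to 10, although it was 0.99 in the dimmest genes. A constant offset of the array is argued against by the list median lying 1.62 above that of all genes. Several of the genes as bright also serve translation (eef2b, rack1, faua, naca). Among them rps27.1 and rps26l carry ribosomal protein names that the patterns of the list missed. Higher transcription of this machinery in the lens therefore stays open and untested.

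Fewer probes were well above background on the lens array, and 2 technical explanations were set against it. Lower sensitivity of hybridization or scan is argued against by 8 spike-in probes that were brighter on the lens array by a median of 1.31 (0.43 to 1.54), beyond their greatest spot spread of 0.27, if equal amounts of spike-in were added. Crystallin transcripts crowding out the rest stay open: their 17.5% of the gene signal (1 probe per gene) would dilute the rest by 0.28 on the log2 scale against a shift of 2.13 in the 75th percentile, but summed signals of different probes do not measure a share of RNA. A smaller amount of labelled lens RNA against the spike-ins could also give fewer such probes and was not tested. The tissue itself, with fewer cell types and so fewer genes transcribed, also stays open.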
